A study of Mus musculus with 4 samples.

How the data were processed

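Total RNA was extracted from sorted DN4 thymocytes of 4 mice, amplified in a 2-cycle biotin labelling and hybridised to Affymetrix mouse gene arrays, 1 array per mouse, per the labels' protocols. The labels state different amounts of input RNA for 3 codes and do not tie these codes to the mice. The deposited values are log2 expression values, 1 per probe set and mouse, which the authors made with RMA per the submitters' processing notes. The log2 scale is read from the values, which lie between 3.14 and 14.4 with near-equal quartiles on the 4 arrays. The version of RMA, any filter and the genome build are not given in the sources used here, so no coordinates are given. No further normalization was applied, and 0 sample columns were left unused.

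Samples were grouped by the Cre status in their titles, with 2 Cre+ mice (129 and 135) and 2 Cre- mice (131 and 137) as separate animals, and no number pairs a mouse of one group with a mouse of the other. Genes were named through the platform annotation, in which 21789 probe sets had exactly 1 gene symbol (19938 different genes), 1621 had several and 12146 were not listed. Symbols were looked up by gene number in a table of RefSeq genes. This found 21698 of them and changed 0. No gene was named from a probe set with several symbols, so some genes of the lists were not used here. Probe sets not listed are unnamed here.

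All probe sets were compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all 35556 probe sets and a threshold of 0.05. There were 2 residual and 2.99 prior degrees of freedom. Differences are Cre+ minus Cre- on the log2 scale with limma's moderated standard error. With 2 against 2 mice there are 3 splits, and no exact two-sided permutation test could give a p under 0.333, so p-values rest on limma's pooling of the spread across probe sets.

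Before the data were examined, 30 gene lists with 585 different genes were fixed, of which 524 were measured. They cover T cell stages and signalling, Notch, the Ikaros family, other cell types, metabolism, stress responses and chromatin complexes. Each was tested with limma's camera on the probe set with the highest mean per gene (19938 genes), with the correlation between members preset to 0.01 and adjustment over the 30 lists. Camera asks whether a list shifts relative to all other genes. The estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. With the preset correlation 12 lists were called. With the estimated correlation 0 lists were called, with 1 at an unadjusted p under 0.05, and with fry 0, with 2 at an unadjusted p under 0.05.

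The genes to name were set by a rule fixed in advance. It took Ikzf1, then the 12 largest rises and 12 largest falls among probe sets with 1 gene symbol past the adjusted threshold whose groups do not overlap. Places left open were filled with the largest differences at an unadjusted p under 0.01 with groups that do not overlap, named as not past the threshold. Since 0 probe sets passed, all 24 were filled in this way. The rule also took the 4 members with the smallest p in each list and any others past the threshold, and 133 different genes were named in all. A gene with several probe sets was represented by the one with the highest mean. Genes named outside this rule are said to have been chosen after their values were seen.

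The tests were checked on simulated data with the same number of arrays. In 5 simulated comparisons of Cre+ against Cre- over 35556 probe sets, 200 probe sets were changed. At an adjusted p under 0.05, limma recovered 58.6% of 2-fold and 96.8% of 4-fold changes, with 9.2 false calls on average. The probe sets were independent and their spread was drawn from limma's own fit. These shares are therefore not the power of the real comparison. In 20 simulated comparisons of 19938 independent genes, a list shifted by -0.3 was called 20 times by camera with the preset correlation, with 1 call of an unshifted list in all. It was called 0 times with the estimated correlation, so that setting can miss such a shift among independent genes. Lists with correlated members, and fry, were not simulated, so what a lost call means for the real lists cannot be told. In the real lists the estimated correlation reached 0.78, for interferon response genes. The 1 false call therefore does not carry over to them. With the preset correlation, camera's p-values rest on the number of genes and do not measure how far lists vary between mice. They are too small for that use. With mice 129 and 137 against 131 and 135, which follows neither Cre nor sex, 7 lists were still called.

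The alternatives were centring of the arrays, quantile normalization again, cyclic loess, filters on dim probe sets at the 25th percentile and at the median, eBayes without trend or robust, array weights, a test limited to probe sets with 1 gene symbol, a test without Xist and Y-linked genes, other thresholds, the mean of all probe sets of a gene, and leaving out each mouse in turn. Without a mouse, the lone mouse of its group is assumed to vary like the other group. The sex of the mice as a block, and all variations of the test limited to 1 gene symbol, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.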

Results

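Gene expression was measured in DN4 thymocytes, the last of the immature thymic stages that lack both CD4 and CD8, sorted from 4 mice with floxed alleles of Ikzf1, the gene of the zinc-finger transcription factor Ikaros. All 4 mice received tamoxifen at 50 mg/kg daily for 4 days and were analysed 24 h after the last injection. In 2 of them (mice 129 and 135, Cre+) a tamoxifen-inducible Cre recombinase expressed from the Rosa26 locus could excise the floxed alleles, and in the other 2 (mice 131 and 137, Cre-) no such recombinase was present. Per the series' design text, western blots of the sorted Cre+ cells showed that the Ikaros protein was lost. Each mouse gave 1 array, with log2 values between 3.14 and 14.4 and array medians between 6.85 and 6.88. The number of arrays, 2 in each group, limits the precision of every value.

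The 4 arrays resembled each other closely. Pearson correlations across probe sets, which are not independent replicates, ranged from 0.994 to 0.997. Over the 21789 probe sets with 1 gene symbol, the SD of the difference between arrays was 0.151 for the 2 Cre+ mice and 0.179 for the 2 Cre- mice. Between mice of different groups it ranged from 0.176 to 0.222. Over all probe sets the SD was 0.199 for the 2 Cre+ mice and 0.251 for the 2 Cre- mice. Between mice of different groups it then ranged from 0.217 to 0.269, so the 2 Cre- mice lay within that range. Over probe sets without a listed gene it was 0.266 for the 2 Cre+ mice and 0.339 for the 2 Cre- mice. The latter was above the 0.258 to 0.329 between mice of different groups. Mice 129 and 131 were female and mice 135 and 137 male by their transcripts. Xist, the transcript of the inactive X chromosome, was at 12.51 and 12.34 in the first pair and at 5.29 and 4.93 in the second. The Y-linked gene Kdm5d was at 5.27 and 5.02 in the first pair and at 8.61 and 8.85 in the second, so each group held 1 female and 1 male.

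The targeted gene was compared first. Ikzf1 was at 12.06 and 11.99 in the Cre+ mice and at 12.07 and 12.11 in the Cre- mice. The difference was -0.07 on the log2 scale (SE 0.04), with an adjusted p = 0.925 from limma. Where the array's probes lie relative to the floxed part of the gene was not analysed here, so this value neither checks the labels nor measures the deletion. Of the other family members, Ikzf3, which encodes Aiolos, was higher by 0.90 (SE 0.09, 1.86-fold). It was at 11.53 and 11.44 in the Cre+ mice against 10.46 and 10.71 in the Cre- mice. Ikzf3 did not pass limma's threshold over all probe sets (adjusted p = 0.123) and passed it among probe sets with 1 gene symbol (adjusted p = 0.00184). Ikzf4 differed by 0.22 (SE 0.13) and Ikzf2 by 0.04 (SE 0.07). The family list of 5 genes was not called by camera (median 0.04, adjusted p = 0.0556). It was called higher without mouse 135 (median 0.06, adjusted p = 0.00890) and without mouse 137 (median 0.09, adjusted p = 0.0199), and its median was -0.0027 without mouse 131. It was also called after centring of the arrays (adjusted p = 0.0386), with array weights (0.0444) and with sex as a block (0.0350).

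The main question of the design was which genes differ between Ikaros-deleted and control DN4 cells. The 4 largest differences among the named genes were higher values in Cre+ cells. Ctnnd1, which encodes the junctional protein p120 catenin, was 6.96-fold higher in Cre+ cells, with a log2 difference of 2.80 (SE 0.17). Ifitm3, an interferon-induced membrane protein gene, was 6.16-fold higher (2.62, SE 0.42). Dock1, which encodes a guanine nucleotide exchange factor for Rac, was 5.79-fold higher (2.53, SE 0.13), and the islet autoantigen gene Ica1 was 4.00-fold higher (2.00, SE 0.10). The largest differences in the other direction were those of the beta-tubulin gene Tubb2b 2.94-fold lower (-1.56, SE 0.10) and the endolysosomal channel gene Mcoln3 2.63-fold lower (-1.40, SE 0.27). In the Cre- mice Ctnnd1 was at 5.82 and 5.38 and Dock1 at 5.83 and 5.87, close to the 5.29 and 4.93 of Xist in the male mice. Signal over background was not analysed here, so that these folds describe the RMA values and not transcript numbers.

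None of these genes passed the adjusted threshold over all probe sets. With limma, 0 probe sets had an adjusted p under 0.05, the smallest being 0.0570, while 2356 had an unadjusted p under 0.05 against 1778 expected by chance. Setting the female mice 129 and 131 against the male mice 135 and 137 gave 2567 at that unadjusted p, so such an excess is not particular to Cre. In the comparison of Cre+ with Cre-, 44 probe sets had an adjusted p under 0.1, 40 higher and 4 lower. When the test was limited to the 21789 probe sets with exactly 1 gene symbol, an alternative set before the data were examined, 266 probe sets passed at an adjusted p under 0.05, of which 204 were higher and 62 lower in Cre+ cells. They belonged to 251 different genes. Probe sets without a listed gene varied more, with a median SD within groups of 0.123 against 0.0726 for those with 1 gene symbol. Without mouse 129 the restricted test called 138 probe sets, without mouse 131 it called 480, and without an intensity trend 130; of the 266, it called 121, 245 and 129 again. In what follows, values said to pass in the restricted test are those called among probe sets with 1 gene symbol.

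The 12 genes with the largest higher values also included Socs2, a feedback inhibitor of cytokine receptor signalling (1.88, SE 0.45), and the zinc-finger gene Zfp948 (1.85, SE 0.17). Mpzl2, which encodes an adhesion molecule expressed in the thymus, was higher by 1.79 (SE 0.13) and the calcium-binding protein gene S100a1 by 1.70 (SE 0.15). Maged1 was higher by 1.69 (SE 0.14), Uaca by 1.62 (SE 0.13), Lmcd1 by 1.57 (SE 0.14) and the endocytic receptor gene Lrp1 by 1.54 (SE 0.17). The 12 with the largest lower values also included 1700048O20Rik (-1.27, SE 0.11) and Fignl1, which acts in homologous recombination (-1.10, SE 0.08). The inhibitory lectin receptor gene Clec12a differed by -1.08 (SE 0.12) and Nkg7, a cytotoxic granule gene of natural killer and T cells, differed by -1.04 (SE 0.09). The tetraspanin gene Cd53 differed by -0.95 (SE 0.17) and the acid-sensing receptor gene Gpr65 by -0.86 (SE 0.10). 5830411N06Rik, AW112010, Tes and Mtrr differed by -0.86, -0.84, -0.79 and -0.76. Of these 24 genes, 13 had an adjusted p under 0.1 over all probe sets, and 23 passed in the restricted test. The exception was Socs2, with an adjusted p = 0.0537 from limma, and its other probe set differed by 0.44 (SE 0.15).

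**Figure D1:**
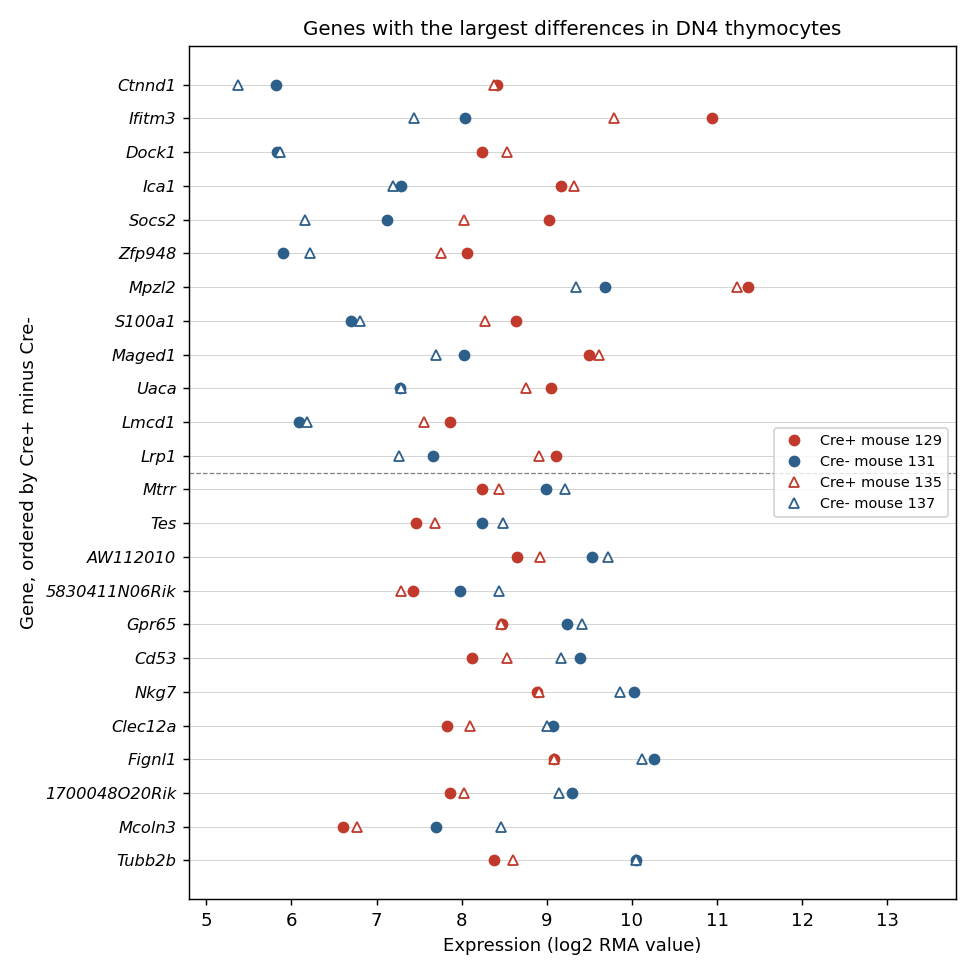
Expression of the 24 genes with the largest differences in each mouse, as log2 RMA values, with genes ordered by the Cre+ minus Cre- difference and a dashed line between higher and lower genes. Each symbol is 1 mouse, and the genes were chosen so that the 2 Cre+ mice lie on one side of the 2 Cre- mice, with differences from 2.80 for Ctnnd1 to -1.56 for Tubb2b.

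Genes of cholesterol synthesis were lower together in Cre+ cells. All 20 measured members of the list had lower means, with a median of -0.35 (1.28-fold), and 16 had an unadjusted p under 0.05 in limma. Lss, which encodes lanosterol synthase, differed by -0.67 (SE 0.10), the farnesyl diphosphate synthase gene Fdps by -0.42 (SE 0.07), Hmgcs1, the cytosolic HMG-CoA synthase gene, by -0.52 (SE 0.09), and the sterol desaturase gene Sc5d by -0.35 (SE 0.06). Adjusted over all probe sets 0 members passed, adjusted over the list alone 16 passed, and 6 passed in the restricted test. The shift was seen in the female pair (median -0.39) and in the male pair (-0.29). Camera called the list (adjusted p = 2.44e-20), and the call was lost with an estimated correlation of the members (adjusted p = 0.627). Camera with that setting called a simulated list shifted by -0.3 in 0 of 20 data sets. The simulated genes were independent, so this cannot show what a lost call means for lists whose members vary together, here or below. Fry did not call the cholesterol list either (adjusted p = 0.302).

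Interferon response genes were higher in Cre+ cells. Of 26 measured members, 25 had higher means, with a median of 0.71 (1.64-fold), and 14 had an unadjusted p under 0.05 in limma. Ifih1, the cytosolic sensor of double-stranded RNA, was higher by 1.14 (SE 0.19), the oligoadenylate synthetase gene Oas1a by 0.87 (SE 0.15), the immunity-related GTPase gene Irgm1 by 0.61 (SE 0.12), and Xaf1 by 0.97 (SE 0.22). The first 3 of these passed in the restricted test, as 3 members did in all, and 11 passed adjusted over the list alone. Camera called the list (adjusted p = 9.56e-20), and the call was lost with an estimated correlation (adjusted p = 0.627) and with fry (adjusted p = 0.416). Camera also called it with mice 129 and 131 against 135 and 137 (median 0.34, adjusted p = 0.000873). The same held with mice 129 and 137 against 131 and 135 (median 0.34, adjusted p = 5.56e-05). A call of this list is thus not particular to Cre. The size of the shift between Cre+ and Cre- depended on mouse 129. Relative to the mean of the 2 Cre- mice, the median of the list was 0.98 in mouse 129 and 0.36 in mouse 135, while the 2 Cre- mice differed by a median of 0.05.

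**Figure D2:**
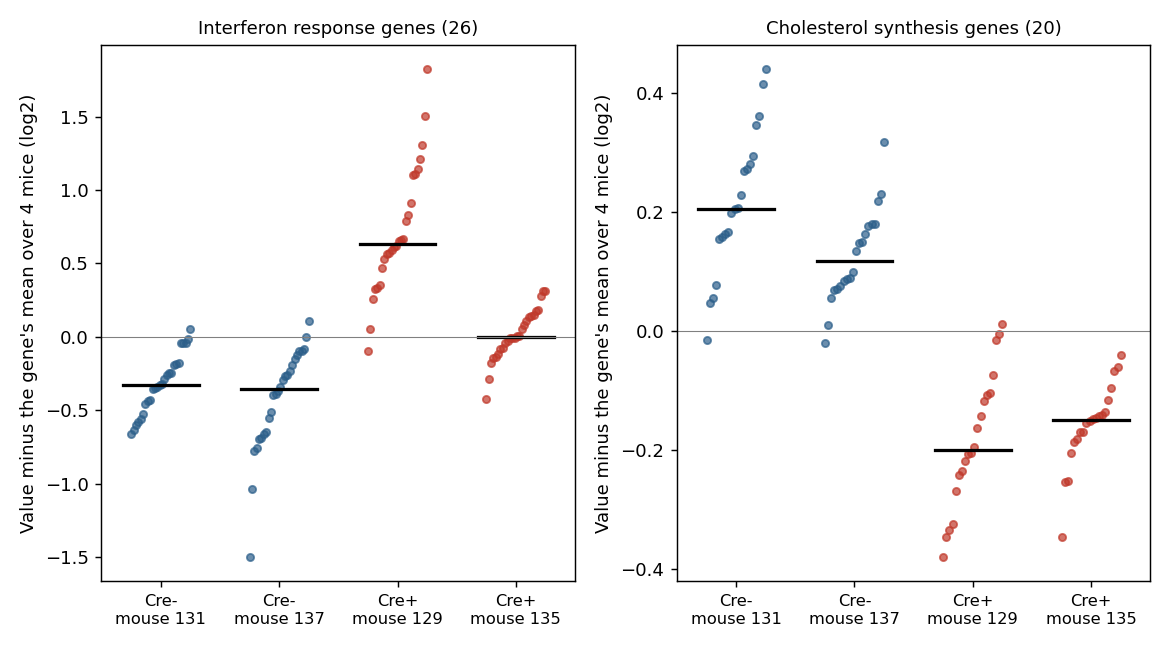
Values of the 26 interferon response genes (left) and the 20 cholesterol synthesis genes (right) in each mouse, as the log2 value minus that gene's mean over the 4 mice. Each point is a gene and each black line the median of a mouse, which for the interferon list is 0.63 in mouse 129, -0.00 in mouse 135, -0.32 in mouse 131 and -0.36 in mouse 137, and for the cholesterol list -0.20, -0.15, 0.21 and 0.12.

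Genes tied to the pre-TCR stage and to the T cell receptor complex were compared as 5 lists. Hes1, a transcriptional repressor induced by Notch, was at 11.25 and 11.24 in the Cre+ mice and at 10.35 and 10.32 in the Cre- mice, a difference of 0.91 (SE 0.05). Its adjusted p was 0.0570 over all probe sets, and it passed in the restricted test (limma, adjusted p = 0.000467). The list of Notch targets as a whole was not called (median 0.00, 9 higher and 9 lower, camera adjusted p = 0.584), and its median was -0.05 without mouse 129, -0.06 without mouse 131, 0.03 without mouse 135 and 0.04 without mouse 137. Ptcra, the pre-TCR alpha chain gene, differed by 0.33 (SE 0.07) and the fringe gene Lfng by 0.53 (SE 0.14), while Cd44 differed by -0.42 (SE 0.10), and none of these 3 passed in the restricted test. The list of DN2 and DN3 stage genes was not called either (median -0.02, mean 0.04, 9 of 19 higher, adjusted p = 0.226), but it was called higher without mouse 135 (median 0.00, adjusted p = 0.0347) and among genes above the median level (median 0.03, adjusted p = 0.0184). Its median was -0.04 without mouse 129 or 137 and 0.01 without mouse 131. Its members Rag1, the recombinase gene (0.38, SE 0.08), and Dntt, which encodes terminal transferase (0.21, SE 0.03), passed in the restricted test. Among Notch receptors and cofactors (20 genes, median 0.01, adjusted p = 0.584) Rbpj differed by 0.15 (SE 0.06) and by 0.01 in its other probe set, Notch1 by 0.21 (SE 0.08), Maml1 by 0.22 (SE 0.11) and Adam17 by -0.12 (SE 0.07).

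The T cell receptor signalling list was called higher by camera, with 17 of 23 members higher and a median of 0.06 (adjusted p = 0.00103). With an estimated correlation the adjusted p = 0.776. The CD3 chain genes Cd3d, Cd3g and Cd3e led it, with Cd3d higher by 0.66 (SE 0.08), Cd3g by 0.37 (SE 0.05) and Cd3e by 0.25 (SE 0.04), together with the kinase gene Fyn by 0.42 (SE 0.06). These 4 passed in the restricted test and adjusted over the list alone. Cd247, the CD3 zeta chain gene, chosen after its values were seen, differed by -0.10 (SE 0.06) without passing. The median was 0.00 without mouse 131 (adjusted p = 0.370) and -0.00 without mouse 129 (adjusted p = 0.0655), and it was 0.13 without mouse 135 and 0.12 without mouse 137. The DP stage list, named for the double-positive stage that follows DN4, was called higher with 13 of 20 members higher (median 0.05, camera adjusted p = 0.0106; adjusted p = 0.724 with an estimated correlation). The members differed in direction. Ikzf3 and Rag1 were higher and the chemokine receptor gene Ccr9 lower (-0.64, SE 0.08), each passing in the restricted test, while Cd4 differed by 0.54 (SE 0.11) without passing. This call was lost without mouse 131 (adjusted p = 0.395).

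Immediate early genes, which respond within minutes to receptor signals and to cell handling, had higher means in 25 of 26 cases (median 0.23, camera adjusted p = 3.14e-09; adjusted p = 0.652 with an estimated correlation). No member passed over all probe sets, adjusted over the list alone or in the restricted test. Ier3 differed by 0.62 (SE 0.14), Ier2 by 0.54 (SE 0.15), the nuclear receptor gene Nr4a1 by 1.01 (SE 0.33) and Socs3 by 0.44 (SE 0.15), or by 0.05 in its other probe set. The shift rested largely on Cre- mouse 131, being 0.09 without it and 0.43 without mouse 137. Nr4a1 was at 9.09 in mouse 131 and between 10.11 and 10.71 in the other mice. In the same mouse the heat-shock gene Hspa1a was at 8.43, against 11.51 and 12.14 in the Cre+ mice and 12.36 in mouse 137. The heat shock list was not called (14 genes, median -0.02, mean 0.08, adjusted p = 0.637), and Hspd1, Hsph1 and Hsp90aa1 differed by -0.10, -0.23 and -0.06. Without mouse 135 it was called lower (median -0.07, adjusted p = 0.0300).

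Several lists of growth, metabolism and stress genes shifted by less. MYC and ribosome biogenesis genes had lower means in 18 of 21 cases, and none passed over all probe sets, adjusted over the list alone or in the restricted test. The difference was -0.13 for the spermidine synthase gene Srm, -0.17 for Polr1b, -0.32 for Rrs1 and -0.16 for Bop1. Camera called the list lower (median -0.07, adjusted p = 3.34e-05, or 0.627 with an estimated correlation). Without mouse 131 this median was -0.04. Glycolysis genes had lower means in 12 of 17 cases. None passed over all probe sets or in the restricted test, and 2 passed adjusted over the list alone. The difference was -0.38 for the glucose transporter gene Slc2a3, -0.25 for Pkm, -0.14 for Pgam1 and -0.12 for Aldoa. Camera called this list lower too (median -0.08, adjusted p = 0.00146, or 0.627 with an estimated correlation). That call was lost without mouse 131 (adjusted p = 0.128), and the median was -0.05 without mouse 135. The p53 target list was called higher with 17 of 23 members higher (median 0.07, camera adjusted p = 0.000850; adjusted p = 0.627 with an estimated correlation). Its member Pmaip1, which encodes the BH3-only protein Noxa, was higher by 0.61 (SE 0.11) and passed in the restricted test, while Ei24, Tnfrsf10b and Trp53inp1 differed by 0.25, 0.34 and 0.33 without passing. This call was lost without mouse 131 (adjusted p = 0.0923), and the median was 0.12 among genes above the median level. Proliferation genes were not called, with 10 of 31 higher and a median of -0.01 (camera adjusted p = 0.584), and Ccne1, Tyms, Rrm2 and Mcm2 differed by -0.17, 0.11, -0.09 and -0.07. They were called lower without mouse 135 (median -0.04, adjusted p = 0.00532), and their median was 0.01 without mouse 129. Apoptosis regulators were not called either (19 genes, median 0.07, adjusted p = 0.0621), with 0.61 for Pmaip1, 0.27 for Xiap, 0.14 for Bak1 and 0.28 for Bmf. They were called higher without mouse 135 (median 0.04, adjusted p = 0.0451), without mouse 137 (median 0.07, adjusted p = 0.00785) and with the mean of all probe sets of a gene (adjusted p = 0.0479).

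Markers of mature T cells and thymic egress had lower means in 12 of 16 cases (median -0.20, camera adjusted p = 0.000134, or 0.683 with an estimated correlation). Their median was -0.32 among genes above the median level. Ms4a4b differed by -0.56 (SE 0.09) and was the only member to pass in the restricted test. It was at 5.52 and 5.39 in the Cre+ mice and at 6.02 and 6.02 in the Cre- mice, below the array medians. Runx3, a transcription factor of the CD8 lineage, differed by -0.69 (SE 0.16), Gimap6 by -0.39 (SE 0.11) and Ms4a6b by -0.28 (SE 0.08) without passing. Cytokine and chemokine receptor genes had lower means in 21 of 29 cases (median -0.10, camera adjusted p = 0.00127, or 0.627 with an estimated correlation). The interleukin-12 receptor genes Il12rb1 (-0.73, SE 0.15) and Il12rb2 (-0.49, SE 0.08) and Ccr9 passed in the restricted test, as did Il6st, the shared gp130 chain gene, in the other direction (0.47, SE 0.08). T lineage transcription factor genes were called higher (16 of 23 higher, median 0.05, camera adjusted p = 0.0363; adjusted p = 0.776 with an estimated correlation). The call was lost without mouse 129 (median 0.02, adjusted p = 0.202) and without mouse 131, where the median was -0.04 (adjusted p = 0.926), and the median was 0.09 without mouse 135 and 0.10 without mouse 137. It was also lost with cyclic loess (adjusted p = 0.0505), without an intensity trend (0.114), and among genes above the 25th percentile of level (0.0741) or above the median level (0.0625). In that list the member with the smallest p, Runx3, went the other way (-0.69), while Ets2 differed by 0.37, Ets1 by 0.18 and Runx1 by 0.12, none passing in the restricted test.

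Markers of other cells that the sort could have held were compared in the same way. The B cell list was called lower, with 14 of 19 members lower (median -0.18, camera adjusted p = 0.0473; adjusted p = 0.627 with an estimated correlation). The call was lost without mouse 129 (adjusted p = 0.202) and without mouse 137, where the median was -0.09 (adjusted p = 0.369). It was also lost among genes above the 25th percentile of level (median -0.12, adjusted p = 0.319) or above the median level (median -0.03, adjusted p = 0.926), and with the mean of all probe sets of a gene (adjusted p = 0.0644). Its most changed member went the other way. Igll1, the lambda5 chain of the surrogate light chain, was higher by 1.38 (SE 0.11, 2.60-fold) and passed in the restricted test, as the kinase gene Blk did at -0.51 (SE 0.09), while Cd79a and Cd79b differed by -0.35 and 0.25. Dendritic cell markers were not called (18 genes, median -0.02, adjusted p = 0.584; -0.05 without mouse 129 and -0.04 without mouse 135), and Ccr9, at -0.64, was also among them. The class II genes H2-Aa and Cd74 were highest in Cre- mouse 137, at 7.73 and 8.28, against at most 6.67 and 7.45 in the other mice, and Tcf4 was higher by 0.39 (SE 0.07), passing in the restricted test. Myeloid markers were not called (24 genes, median 0.01, adjusted p = 0.825). Their member Lyz2, the lysozyme gene of macrophages, was higher by 1.04 (SE 0.18) and passed in the restricted test, while Fcgr2b, C1qc and C1qb differed by -0.27, 0.18 and 0.26.

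Natural killer and innate lymphoid markers were not called (20 genes, median 0.02, mean -0.03, camera adjusted p = 0.825), and besides Nkg7 the granzyme gene Gzma differed by -0.19, Tbx21 by 0.36 and Il2rb by 0.21. Their median was between -0.03 (without mouse 135) and 0.02 (without mouse 129) when 1 mouse was left out. Gamma delta T cell markers were not called (11 genes, median -0.03, adjusted p = 0.344), with -0.51 for Blk, which passed in the restricted test, -0.42 for Cd44, 0.29 for Il17re and 0.46 for Id3. Their median was -0.12 without mouse 129, -0.09 without mouse 137, -0.02 without mouse 135 and 0.0026 without mouse 131. Erythroid markers (9 genes, median 0.02, mean -0.03, adjusted p = 0.584) included Tfrc at -0.25, Car2 at 0.21, Gata1 at -0.13 and Epb42 at -0.10. Thymic stroma markers (20 genes, median -0.01, mean 0.01, adjusted p = 0.827) included Cldn4 at 0.44, Epcam at -0.48, Pdgfrb at 0.43 and Krt18 at 0.18. Stem and progenitor genes (22 genes, median -0.01, adjusted p = 0.827) included Gfi1b at 0.61, Bcl11a at -0.58, Hoxa9 at -0.12 and Mef2c at -0.12. The sex-linked list (4 genes, median 0.08, adjusted p = 0.873) was not called, and Uty and Eif2s3y differed by 0.05 and 0.10.

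Integrin and adhesion genes moved in both directions and were not called as a list (24 genes, 8 higher, median -0.04, mean 0.02, camera adjusted p = 0.825). In the restricted test 5 members passed as higher and 1 as lower. Itga6, the integrin alpha6 gene, was higher by 0.99 (SE 0.06, 1.98-fold), the activated leukocyte adhesion molecule gene Alcam by 0.77 (SE 0.10) and the tetraspanin gene Cd81 by 0.76 (SE 0.08), while Itga4, the integrin alpha4 gene, differed by -0.50 (SE 0.05). Genes of chromatin complexes were not called as lists. For the NuRD complex, in which Ikaros is found (14 genes, median -0.02, camera adjusted p = 0.232), Mta3 differed by -0.20 and by -0.06 in its other probe set, Chd3 by -0.25, Mbd2 by -0.07 and Chd4 by 0.06. For the Polycomb complexes (26 genes, median 0.03, adjusted p = 0.584) Phc1 differed by 0.25, Pcgf2 by 0.32, Mtf2 by -0.13 and Pcgf5 by -0.15.

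**Figure D3:**
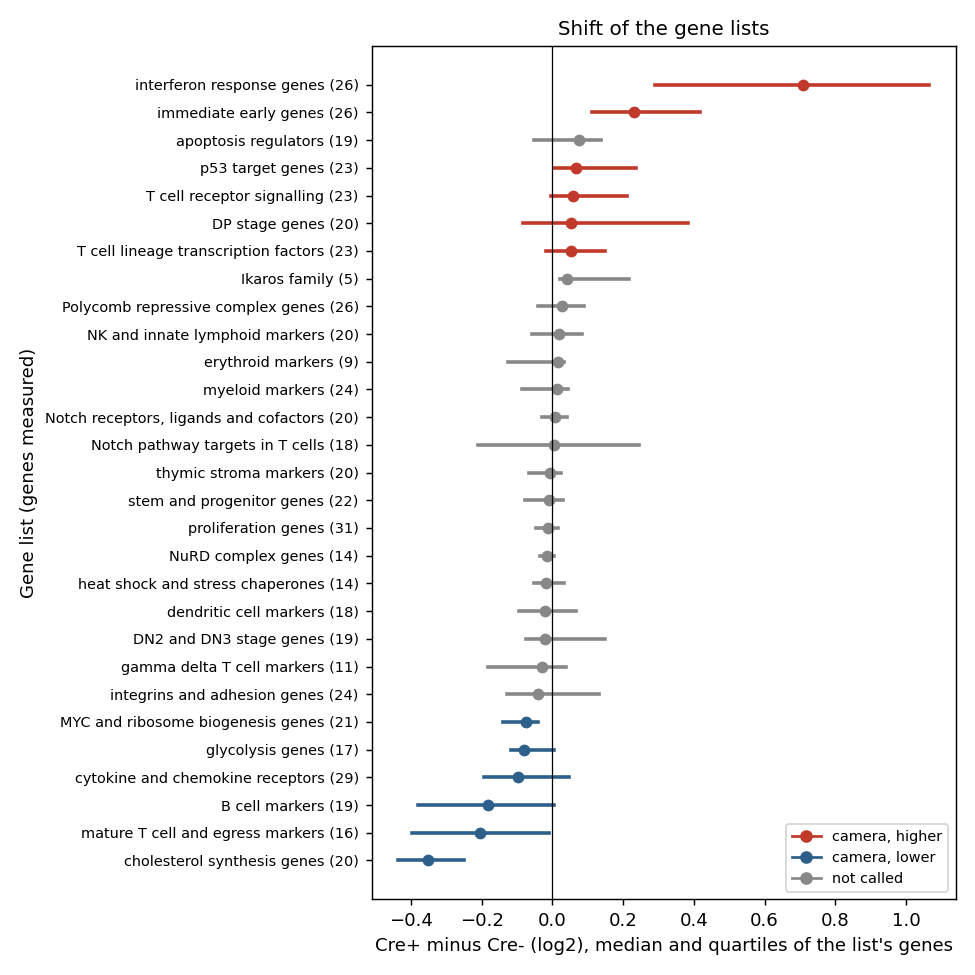
Log2 difference between Cre+ and Cre- mice in 29 gene lists, with the median of the measured genes as a point and their quartiles as a line, and the number of genes measured in parentheses. Colours mark the 12 lists called by camera with a preset correlation, 6 higher and 6 lower. Their medians ranged from 0.71 for interferon response genes to -0.35 for cholesterol synthesis genes. None of these calls held with an estimated correlation, which also called a simulated list shifted by -0.3 in 0 of 20 data sets of independent genes.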

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

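The tests on mouse 129, on dendritic, cycling, DN3 and CD8-positive cells, on Cre recombinase and on the splits over all probe sets were chosen after the results were seen, unlike those on random lists and on the splits for lists and for probe sets with 1 gene symbol. Among the lists called by camera, 2 moved in opposite directions in the female and the male pair of mice, and the difference between the pairs was not tested. The median of the T cell receptor signalling list was 0.17 in the female pair (mouse 129 minus mouse 131) and -0.048 in the male pair (mouse 135 minus mouse 137). Of its 23 genes, 19 were higher in the female pair and 8 in the male pair. The median of the T lineage transcription factor list was 0.12 in the female pair and -0.051 in the male pair, with 18 and 8 of 23 genes higher.

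Whether the groups differ more than other splits of the 4 mice was counted. The 3 splits are too few for a share under 0.05. Over all probe sets the real split gave 0 probe sets with limma (2356 at an unadjusted p under 0.05) and the highest of the others gave 5, when mice 129 and 131 were set against mice 135 and 137. At an unadjusted p under 0.05 that other split gave 2567, more than the real one. A count of 0 is met by 3 of 3 splits whatever the data, and at an adjusted p under 0.1 the real split gave 44 and the others 5 and 0. The split with 5 follows the sex of the mice, and with sex as a block the real comparison again gave 0. Among probe sets with 1 gene symbol the real split gave 266 and the highest other 4, which were Xist, Kdm5d, Eif2s3y and Uty, so that 1 of 3 splits gave as many. With sex as a block it gave 565. For the lists the real split gave 12 calls and the highest other 7, again 1 of 3. The 7 lists called with mice 129 and 137 against mice 131 and 135 held 6 of the 12, namely interferon response, immediate early (adjusted p = 2.34e-08), DP stage, mature T cell, T cell receptor signalling and T lineage transcription factor genes, besides proliferation genes. The interferon list was called in all 3 splits.

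The higher interferon response genes in Cre+ cells were set against 3 explanations. A response of mouse 129 alone would leave mouse 135 at the level of the Cre- mice. In mouse 135 the list's median was 0.36 above the mean of the Cre- mice (SE over members 0.08), with 23 of 26 genes higher. Here and below, an SE over members is a spread of genes and not of mice. The list was thus also higher in mouse 135, but whether by more than mice vary cannot be told from 1 mouse. Dendritic cells carried over in the sort would raise their markers together, whereas the dendritic cell list without interferon list genes had a median of -0.024 (SE over members 0.064), which argues against them as the whole cause. Single members went both ways, with 0.39 for Tcf4, 0.22 for H2-Ab1 and 0.07 for Irf8 (the last 2 chosen after their values were seen). H2-Aa differed by -0.57 and Cd74 by -0.47, which were 0.0052 and 0.099 without mouse 137. H2-Aa was at 6.51, 6.59 and 6.67 in mice 129, 131 and 135, below the array medians. An effect of Cre recombinase or of its activation cannot be told apart from loss of Ikaros, since every Cre+ mouse also carried floxed alleles, and the p53 target list, which DNA cutting by Cre could raise, had a median of 0.067.

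The lower cholesterol synthesis genes were set against 2 explanations. A scaling difference that depends on signal level goes against random lists matched on mean expression, since the lowest median of 10000 such lists was -0.10 and that of the cholesterol list was -0.35. A smaller share of cycling cells goes against the proliferation list, whose median was -0.012 (SE over members 0.011), and -0.040 without mouse 135, where it was called lower while the cholesterol list stood at -0.36. That loss of Ikaros lowers this pathway is a hypothesis drawn from these same mice and was not tested. An effect of Cre recombinase, for which no control is among the 4 mice, stays open.

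Hes1, Ptcra, Igll1, Rag1, Cd3d, Cd3g and Cd3e had higher means in Cre+ cells while Cd8a (-0.61, SE 0.21) and Cd8b1 (-0.27, SE 0.08), chosen after their values were seen, were lower without passing in the restricted test. More DN3 cells in the sorted population could give part of this. The DN2 and DN3 list without Hes1, Ptcra and Rag1 had a median of -0.029, with 6 of 16 genes higher, and Il2ra, whose product CD25 marks DN3 and not DN4 cells, differed by -0.38 (SE 0.23). Fewer cells that already express CD8 could give the lower Cd8 values, and the DP list without Cd8a and Cd8b1 had a median of 0.11, with 13 of 18 genes higher. Unlike the DN2 and DN3 list, this list still held Rag1, which is part of the pattern. Both cannot be told apart from a change within DN4 cells, since the members of each list moved in both directions.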

How the results depend on the processing

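Alternatives with sex as a block and those of the test on 1 gene symbol were chosen after seeing the data. Over all probe sets limma called 0 at an adjusted p under 0.05 (2356 at an unadjusted p under 0.05), and 10 after centring the arrays, 25 and 80 with dim probe sets below the 25th percentile or the median removed, and 266 with 1 gene symbol only, where the prior degrees of freedom were 6.12 in place of 2.99. The cause of these increases was not tested. At an adjusted p under 0.1 there were 44, and 86 differed 2-fold with groups apart. The count over all probe sets at an adjusted p under 0.05 was 0 under the other alternatives that kept every mouse. Among probe sets with 1 gene symbol there were 130 without trend, 565 with sex as a block, and 138 to 480 without 1 mouse, and 276 to 326 otherwise. Of the 266, those called again numbered 121 without mouse 129, 172 without mouse 135, 233 without mouse 137 and 245 without mouse 131, 129 without trend and 265 with sex as a block. The lists called numbered 0 with an estimated correlation, 0 with fry, and 7 to 17 without 1 mouse. Ikzf1 ranged from -0.10 to -0.03. The direction of genes whose groups do not overlap cannot turn when 1 mouse is left out. Named genes turned direction only without 1 mouse, where ranges were -0.12 to 0.0044 for Hsp90aa1, -3.44 to 3.97 for Xist, -0.030 to 0.11 for Ikzf2, -0.0081 to 0.13 for Chd4, -0.54 to 3.40 for Hspa1a, -2.45 to 2.65 for Eif2s3y, -2.15 to 2.26 for Uty, -1.91 to 1.92 for Kdm5d, -1.14 to 0.0052 for H2-Aa, -0.0997 to 0.55 for H2-Ab1, -0.013 to 0.15 for Irf8 and -1.04 to 0.099 for Cd74. Camera's direction is that of its test against all other genes, so the sign of a list's median need not turn with it. This direction turned for uncalled lists. The medians were then 0.087 for sex-linked genes after centring, and 0.077 for these and -0.00023 for thymic stroma with cyclic loess. They were 0.018 for myeloid markers above the 25th percentile and 0.044 for stem genes above the median. Without 1 mouse, lists that turned ranged from -0.050 to 0.042 for thymic stroma markers, -0.040 to 0.011 for proliferation genes, -0.070 to 0.025 for heat shock and stress chaperones, -0.072 to 0.0049 for integrins and adhesion genes, -0.014 to 0.034 for Notch receptors, ligands and cofactors, -0.048 to 0.032 for stem and progenitor genes, -0.15 to 0.073 for erythroid markers, 0.012 to 0.030 for Polycomb repressive complex genes, -2.00 to 2.06 for sex-linked genes, -0.035 to 0.10 for T cell lineage transcription factors and -0.035 to 0.0091 for myeloid markers. The cause was not tested. Signal over background was not analysed here.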

Other observations

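The genes in this part were chosen after their values were seen, from those that passed limma's test among probe sets with 1 gene symbol, and none passed over all probe sets. Among genes outside the fixed lists, Ctnna1, which encodes alpha-catenin, was higher by 0.96 (SE 0.09) and the vinculin gene Vcl by 0.86 (SE 0.09). Itgb1, the integrin beta1 gene, was higher by 0.42 (SE 0.06) and Itga5 by 0.50 (SE 0.09), whereas Itga4 differed by -0.50 (SE 0.05) and 16 of the 24 genes of the integrin and adhesion list, which was not called, had lower means. The thymosin genes Tmsb4x and Tmsb10 differed by -0.31 (SE 0.04) and -0.55 (SE 0.11), and the plastin gene Lcp1 by -0.29 (SE 0.03). Other genes with large differences were Cacng4 (1.54, SE 0.09), Ifitm2 (2.83-fold higher, SE 0.16 on the log2 scale), the neighbouring pair Tmem176a (1.41, SE 0.10) and Tmem176b (1.38, SE 0.10), Lxn (1.33, SE 0.06) and Cd200 (1.29, SE 0.11).

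Abcg1, a cholesterol exporter gene, was higher by 0.59 (SE 0.07) and the apolipoprotein gene Apoe by 0.69 (SE 0.10). Among the synthesis list, Insig1, which retains the sterol sensor in the endoplasmic reticulum, differed by -0.52 (SE 0.10), Idi1 by -0.50 (SE 0.10; -0.42 in its other probe set, which did not pass) and Fdft1 by -0.39 (SE 0.08), and the fatty acid binding protein gene Fabp5, outside it, by -0.62 (SE 0.07). No enrichment was tested for genes outside the fixed lists.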
